A study of Mus musculus with 4 samples.

How the data were processed

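Total RNA was extracted with the RNeasy Plus Mini kit and made into libraries with the NEBNext Ultra Directional kit, per the labels' protocols. The 4 libraries fall into 2 groups by their titles, 2 with the NC shRNA and 2 with the shRNA against Setdb1. FastQC, STAR, RSEM and DESeq2 and the builds GRCm38 and mm10 are named in the submitters' processing notes, with no versions or roles. The annotation release, the read filters and the strand setting are not given in the sources used here. Each deposited file holds, per the file headers, a row per gene with its length, effective length, expected count, TPM and FPKM, the columns that RSEM writes. The deposited expected counts are estimates in which a read that fits several features is divided among them, so they need not be whole. The deposited TPM values are scaled to the same sum in each library after division by effective length. The deposited FPKM values were not used. RSEM shares reads between near-identical genes by an estimate, so values of paralogs and overlapping genes are less certain, and a gene and its antisense partner can be told apart only if strand was used in counting.

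All 4 files hold the same 115821 rows, of which 54838 are Ensembl genes with symbols and 60983 are loci named by position. Of the gene identifiers 54723 matched GENCODE M21 (GRCm38) without their version, and that annotation gave coordinates, gene types and the place of each locus. No row without a name was found. Expected counts were rounded to whole numbers, and library sizes were the sums over all rows, 19600142, 19513567, 19615440 and 19569013 for control 1, control 2, knockdown 1 and knockdown 2. At this depth 1 CPM is about 19.5 counts. A count was called whole when it lay within 0.005 of an integer.

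Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM normalization, filterByExpr with its default settings, design with the group alone), which left 12821 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual and 7.52 prior degrees of freedom and a biological coefficient of variation of 13.6%. An exact permutation of 2 against 2 libraries cannot give a p below 0.333, so no such test of single genes was used. CPM values are given as mean ± SD over 2 libraries. SEs of log2 fold changes were taken from the F statistic. For genes and loci with 1 to 3 control counts the ratio of summed counts is given with an exact 95% binomial interval, and for 0 control counts a lower bound against 3 counts.

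Before the data were examined, 38 gene lists were fixed. Lists with at least 5 tested members, 37 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 37 lists. Camera called 9 lists higher and 3 lower. With the correlation estimated for each list 0 were called (smallest unadjusted p 0.0804), and fry called 0. Genes named in the text were chosen by a rule also fixed before the data were examined. It takes Setdb1, the 10 largest increases and 10 largest decreases among called genes with separated libraries and a mean of at least 5 CPM over the 4 libraries, the 5 smallest p-values in each direction under the same conditions, and up to 4 called genes with the smallest p for each list that passed the list test or had at least 3 called members. Predicted, unnamed and mitochondrial genes were left out of the lists by size and p. Genes outside this rule are said to be chosen after their values were seen.

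The position-named loci were tested after the rows of the files had been seen, in an edgeR fit of genes and loci together with adjustment among loci. Loci within 1 kb of each other were joined to count elements. Nearness of genes to loci was compared with Fisher's exact test, and neighbouring genes were counted against 1000 permutations of the calls along the genome.

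The gene and list tests were checked on counts simulated for the 12821 genes from their means over the 4 libraries and the trended dispersions of the fit, with 200 changed genes in each of 3 simulations. On average 68% of 2-fold and 94% of 4-fold changes were recovered with their sign, and 1.22% of the calls were false. Genes of the same level were simulated with the same dispersion, without scatter between genes, so these rates need not hold for the real genes. A list of 25 genes with a shift was called in 3 of 3 simulations, and 0 of 60 unshifted lists were called. The simulated genes varied independently of each other, so this does not check the list test where the genes of a list vary together. Alternatives tried were DESeq2's size factors, no filter and a filter of 1 CPM in 2 libraries, the legacy quasi-likelihood fit, DESeq2 1.42.0 (Wald test), limma-trend on log2(TPM + 1), leaving out mitochondrially encoded genes, leaving out each library, the replicate number as a block, and, added after the data had been seen, genes and loci in one fit and a correction for transcript length and GC content.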

Results

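RNA sequencing was used to compare cells of the mouse liver cancer line Hepa1-6 carrying an shRNA labelled NC (Setdb1 wild type by the labels; called the control here) with Hepa1-6 cells carrying an shRNA against Setdb1. Setdb1 is a histone methyltransferase that places methyl groups on lysine 9 of histone H3 and is known for the silencing of retroelements. Each group held 2 libraries of total RNA, numbered 1 and 2. The libraries held between 19513567 and 19615440 expected counts, so depth differed little between the groups, and 17557, 17569, 18265 and 18100 genes had at least 1 count in control 1, control 2, knockdown 1 and knockdown 2. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Within each group the libraries differed by more than sampling noise (chi-square per gene 26.2 between the controls and 23.8 between the knockdown libraries), so no library was taken for a repeat deposit of another, which does not show separate cultures.

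The comparison asks which transcripts differ when Setdb1 is reduced. Setdb1 itself (chromosome 3, 95323525 to 95357202, minus strand, GRCm38) fell from 55.0 ± 4.99 to 9.82 ± 1.63 CPM (counts scaled by library size; SD, n = 2 per group). The values were 51.47 and 58.53 CPM in the control libraries and 10.97 and 8.665 CPM in the knockdown libraries. Its log2 fold change was -2.49 (SE 0.182, edgeR adjusted p = 1.495e-04), which leaves 17.8% of the control level (95% interval 13.5% to 23.7%). Both knockdown libraries therefore carried less Setdb1 RNA than both controls, as labelled.

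More genes rose than fell with the knockdown. Among 12821 genes tested, 538 were higher and 226 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 2731 had an unadjusted p under that value. All 764 called genes had both knockdown libraries on the same side of both controls. That separation was seen in 51.6% of all tested genes, against 33.3% by chance. At least a 2-fold change was seen in 352 of the higher and 95 of the lower genes, with genes lacking control reads set at a floor of 3 control counts over the group. Protein-coding genes made up 490 of the higher and 219 of the lower genes, and long intergenic noncoding RNAs 18 and 2. The first principal component of the 500 most variable genes held 81.1% of their variance and separated the groups. Picking genes by variance over these same libraries favours genes that differ between the groups, so this share is partly set by the choice. Over genes with enough counts, the chi-square per gene was 34.1 to 71.8 between control and knockdown libraries. Within the groups it was 26.2 and 23.8. Leaving out control 1 raised the calls to 1677 (982 higher and 695 lower), and leaving out knockdown 1 raised the lower calls to 451. Without a filter on low counts 0 genes passed in edgeR, with 3379 at an unadjusted p under 0.05, and limma on log2(TPM + 1) called 334, whereas DESeq2 on the filtered genes called 896.

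Among called genes with a mean of at least 5 CPM, the largest increases were in genes with little RNA in the control cells. Gpx2, a glutathione peroxidase, had 1 count in the 2 control libraries together and 394 in the knockdown libraries, a ratio of 393 (95% counting interval 70.2 to 15600). Grb10, an imprinted gene encoding an adaptor that restrains insulin receptor signalling, rose from 0.484 ± 0.0418 to 33.4 ± 1.86 CPM (log2 fold change 6.09, SE 0.263, adjusted p = 1.421e-05), and lies on chromosome 11. Tat, the tyrosine aminotransferase of hepatocytes, rose by a log2 fold change of 4.85, and Pigz, a mannosyltransferase of glycosylphosphatidylinositol anchors, by 4.76. Rassf4, a Ras association domain protein, rose from 5.41 ± 2.08 to 126 ± 8.996 CPM (log2 fold change 4.54, SE 0.240, adjusted p = 4.443e-05). Ocstamp, known from osteoclast fusion, rose by 4.31, the kidney cadherin Cdh16 by 4.04 and the potassium channel subunit Kcnj8 by 3.42. The fetal growth factor Igf2 rose by 3.30 and the glutathione S-transferase Gstp2 by 3.28, both with fractional expected counts in all 4 libraries, so part of their reads was shared with other features and their values are less certain.

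The decreases were smaller. After Setdb1, the largest among genes with a mean of at least 5 CPM were in the tight junction gene Cldn2 (log2 fold change -1.88, SE 0.286, adjusted p = 0.00563), the apolipoprotein gene Apoc2 (-1.82, with fractional counts in 4 libraries), the metallothionein Mt2 (-1.74), the epidermal growth factor receptor ligand Areg (-1.70), the centrosomal gene Cntrl (-1.64), Vash2 (-1.63), the intestinal-type glucosidase Mgam (-1.62), the basement membrane collagen Col4a1 (-1.58) and Cd274 (-1.57). Cd274, which encodes the immune checkpoint ligand PD-L1, fell from 25.6 ± 0.450 to 8.64 ± 0.985 CPM (SE 0.183, adjusted p = 0.00135). Gimd1 (log2 fold change -1.565) and Sec16b, a gene of endoplasmic reticulum exit sites (-1.29), fell too, both among the smallest p-values of the lower genes. On log2(TPM + 1) Cntrl did not pass (adjusted p = 0.133).

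**Figure D1:**
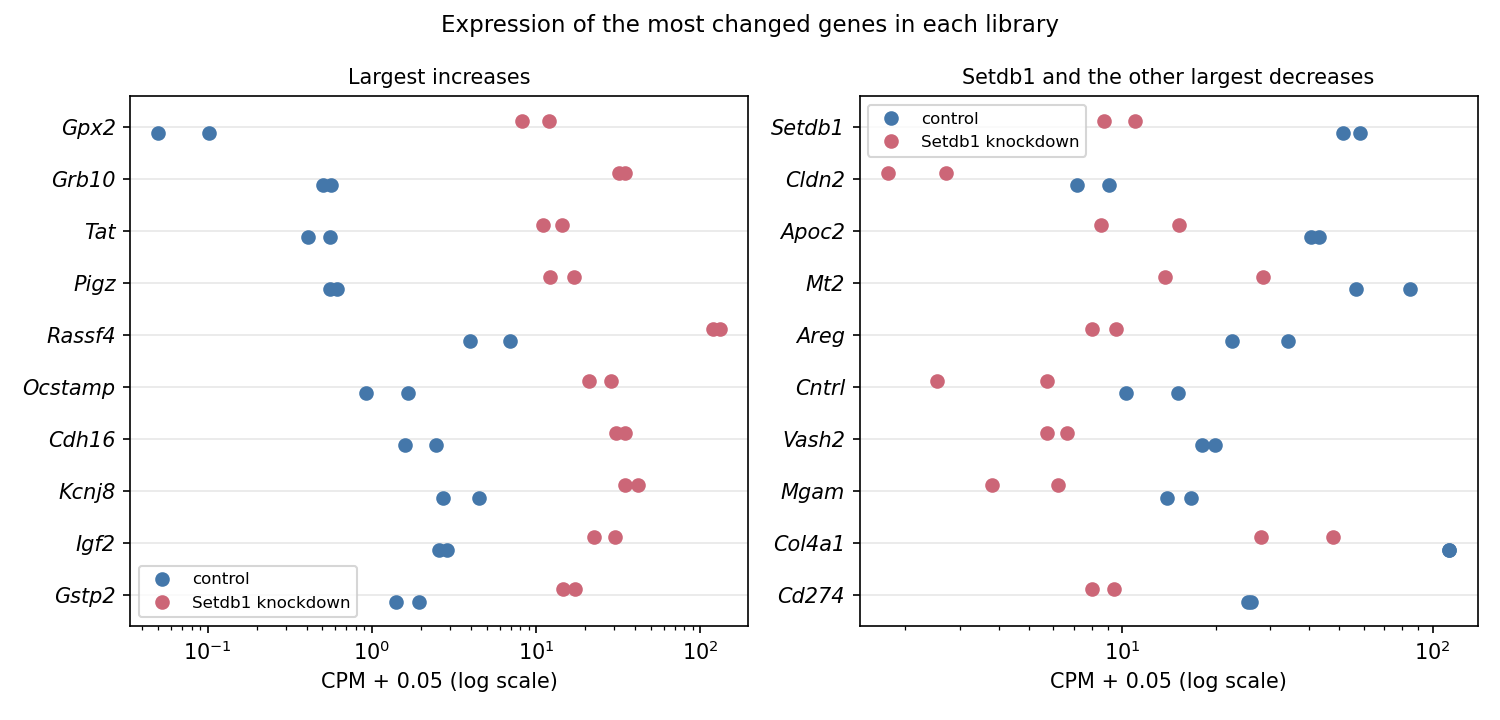
Expression in CPM (with 0.05 added, log scale) of the 10 genes with the largest increases and the 10 with the largest decreases at a mean of at least 5 CPM, one point per library, control in blue and Setdb1 knockdown in red. For each gene the 2 knockdown points lie on the same side of the 2 control points, from Gpx2 with 1 control count in all to Cd274 at 25.6 against 8.64 CPM.

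Cholesterol synthesis genes fell together. Of 26 genes on this list, all tested, 12 fell, 0 rose and 14 did not pass the gene test, and 18 were lower when adjusted over the list alone. Their median log2 fold change was -0.571, with 25 of 26 below 0, and the list passed camera's list test (adjusted p = 3.23e-09 over 37 lists, against adjusted p = 0.826 with an estimated correlation). Fdps, the farnesyl diphosphate synthase, fell from 254 ± 15.96 to 102 ± 24.5 CPM (log2 fold change -1.31, SE 0.173, edgeR adjusted p = 0.00272). Acat2, an acetyl-CoA acetyltransferase, fell by 1.04 on the log2 scale (fractional counts in 4 libraries), and the lanosterol synthase Lss fell by 0.96. The medians against the control mean were -0.538 in knockdown 1 and -0.567 in knockdown 2.

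Fatty acid synthesis genes fell as a list as well (6 lower, 1 higher and 16 neither of 23 tested, 11 lower and 3 higher adjusted over the list alone, median -0.357, camera adjusted p = 0.00568, or adjusted p = 0.826 with an estimated correlation). The phosphatidate phosphatase Lpin1 fell by 1.17, the desaturase Fads2 by 0.83 and the elongase Elovl6 by 0.77 on the log2 scale. Acacb, the acetyl-CoA carboxylase at the mitochondrial surface, rose by 1.94. The call ended without control 1 (adjusted p = 0.105). The glycolysis and hypoxia list passed downward too (median -0.174, adjusted p = 0.00533, or adjusted p = 0.826 with an estimated correlation), with 1 of 32 genes higher, 1 lower and 30 neither, and with 1 higher and 7 lower adjusted over the list alone. Its called members were the glucose transporter Slc2a3, which rose by 2.46, and the angiogenic factor Vegfa, which fell by 0.98 with all libraries and had an adjusted p of 0.0676 without knockdown 2. The list's median against the control mean was -0.074 in knockdown 1 and -0.426 in knockdown 2, and its call ended without knockdown 2 (adjusted p = 0.235) and without control 1 (adjusted p = 0.0793). Elovl6, Lpin1, Vegfa and Acacb did not pass on log2(TPM + 1) (adjusted p from 0.0539 to 0.173).

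Complement and acute phase genes rose. Of 16 tested, 8 rose, 0 fell and 8 did not pass, with 8 higher when adjusted over the list alone (median log2 fold change 0.88, camera adjusted p = 0.00013, or adjusted p = 0.826 with an estimated correlation). Lbp, the lipopolysaccharide binding protein, rose from 22.2 ± 4.20 to 114 ± 11.6 CPM (log2 fold change 2.36, SE 0.174, edgeR adjusted p = 1.495e-04), and ceruloplasmin, Cp, by 1.46. Haptoglobin, Hp, went from 1 count in the controls together to 76 in the knockdown libraries, a ratio of 75.9 (95% counting interval 13.2 to 3040), and complement component C4b from 1 to 66 counts, a ratio of 65.9 (11.4 to 2640). The broader hepatocyte and fetal liver list moved both ways, with 8 of 33 tested genes higher, 4 lower and 21 neither (12 and 5 adjusted over the list alone, median 0.2). It passed upward at a camera adjusted p of 0.0127, or adjusted p = 0.826 with an estimated correlation, and did not pass without control 1 (adjusted p = 0.125) or without knockdown 1 (adjusted p = 0.285). Besides Tat and Hp, heparin cofactor II (Serpind1) rose by 3.98 and hemopexin (Hpx) by 1.42 on the log2 scale. Its lower members, named after their values were seen, were Apoc2, Apoe (-1.18), Apob (-0.74) and the transcription factor Hnf4a (-0.60). Cp and C4b did not pass on log2(TPM + 1) (adjusted p = 0.0771 and 0.115).

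Of 16 genes of cytochrome P450 and other xenobiotic metabolism, 4 rose, 0 fell and 12 did not pass (7 higher and 1 lower adjusted over the list alone, median 0.636, camera adjusted p = 0.0127, or adjusted p = 0.826 with an estimated correlation). The glucuronosyltransferase Ugt2b34 rose by 1.19 and Cyp1a1 by 0.82, both with over 1000 control counts, while Cyp2c38 went from 3 to 43 counts (ratio 14.3, 95% counting interval 4.58 to 72.1). Ugt1a6a, which shares exons with other Ugt1a genes, rose by 2.86 with fractional counts in 3 libraries and did not pass in DESeq2 (adjusted p = 0.538), in the legacy edgeR fit (0.0541) or with the length and GC correction (0.0761). Without knockdown 1 the list had an adjusted p of 0.1. Wnt/beta-catenin targets included 5 higher, 0 lower and 14 other genes of 19 tested (8 higher and 2 lower adjusted over the list alone, median 0.336, camera adjusted p = 0.0202, or adjusted p = 0.826 with an estimated correlation). The Wnt deacylase Notum rose by 2.70, with fractional counts in all 4 libraries and an overlapping antisense gene, Tnfrsf19 by 1.82, the stem cell receptor Lgr5 by 0.99 and the Wnt inhibitor Nkd1 by 0.93. This list did not pass without control 2 (adjusted p = 0.207), without knockdown 1 (adjusted p = 0.145) or without the low-count filter (adjusted p = 0.0514). Cyp1a1, Nkd1 and Cyp2c38 did not pass on log2(TPM + 1) (adjusted p from 0.0592 to 0.0929).

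Interferon-stimulated and antigen presentation genes shifted upward by a small amount. Among 41 tested type I interferon-stimulated genes, 7 rose, 0 fell and 34 did not pass, with 9 higher when adjusted over the list alone (median 0.344, 34 of 41 above 0, camera adjusted p = 0.00013, or adjusted p = 0.826 with an estimated correlation). The apoptosis-linked Xaf1 rose by 1.76, the ADP-ribosyltransferase Parp12 by 0.85, the RNA sensor Ddx58 by 0.73 and galectin 9 (Lgals9) by 0.71. For Ddx58 this was 37.5 ± 2.36 against 62.2 ± 2.56 CPM (SE 0.143, edgeR adjusted p = 0.0176). Of 22 genes of MHC class I presentation, 2 rose, 0 fell and 20 did not pass (6 higher adjusted over the list alone, median 0.347, camera adjusted p = 0.00134, or adjusted p = 0.826 with an estimated correlation). Tapbp, which loads peptides onto class I molecules, rose by 0.98 (fractional counts in 4 libraries). The proteasome activator Psme2 rose by 0.58 with all libraries, with an adjusted p of 0.115 without control 2 and 0.0595 without knockdown 2. The list of nucleic acid sensors was not called (adjusted p = 0.349), with 3 of 21 genes higher and 0 lower (4 higher adjusted over the list alone). These were Ddx58, Tmem173, which encodes STING (log2 fold change 0.75), and Zbp1, which had 4 control counts and did not pass without control 2 (adjusted p = 0.0716), without knockdown 1 (adjusted p = 0.135) or in DESeq2 (adjusted p = 0.0988). With the length and GC correction Zbp1 and Psme2 did not pass (adjusted p = 0.0585 and 0.0757), and on log2(TPM + 1) neither these nor Parp12 and Ddx58 did (adjusted p from 0.0518 to 0.18).

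Of 71 genes on the list of replication-dependent histone genes, only 20 had enough counts to test, so the values speak for these alone. Their median log2 fold change was 1.008, with 3 higher, 1 lower and 16 neither (9 higher and 1 lower adjusted over the list alone). The list passed at a camera adjusted p of 0.00013, or adjusted p = 0.826 with an estimated correlation. Hist1h2bc rose by 1.45, Hist1h2ac by 1.73 and Hist1h2be by 1.79, all from under 6 CPM and with fractional counts in at least 3 libraries, and Hist1h2be did not pass without control 2 (adjusted p = 0.0762), without knockdown 2 (adjusted p = 0.0504) or in DESeq2 (adjusted p = 0.12). The lower member, H1f0, is a replacement linker histone rather than a replication-dependent one and fell by 0.97 from 374 ± 51.3 CPM. In the list of genes known from the mouse 2-cell stage, Usp17ld rose by 3.19 and Usp17lc by 2.08, 5 of 7 tested genes did not pass and 0 fell (2 higher adjusted over the list alone, median 0.683, camera adjusted p = 0.00364, or adjusted p = 0.826 with an estimated correlation). These neighbouring deubiquitinase genes are near-identical copies with fractional counts in all libraries, so their separate values are uncertain. The list did not pass without control 2 (adjusted p = 0.226) or without the low-count filter (adjusted p = 0.0514). Usp17lc, Hist1h2ac and Hist1h2be did not pass on log2(TPM + 1) (adjusted p from 0.054 to 0.0625).

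Mitochondrially encoded genes passed as a list with no gene past the gene test (0 of 15 higher or lower, also when adjusted over the list alone, median 0.429, camera adjusted p = 0.0375, or adjusted p = 0.83 with an estimated correlation). Their share of all counts was 2.29% and 1.67% in the controls and 2.15% and 3.36% in the knockdown libraries, so the groups overlapped. The list did not pass without control 2 (adjusted p = 0.709), without knockdown 2 (adjusted p = 0.369) or without the low-count filter (adjusted p = 0.0568). With a correction for transcript length and GC content its median went from 0.429 to 0.184 and it did not pass (adjusted p = 0.27).

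**Figure D2:**
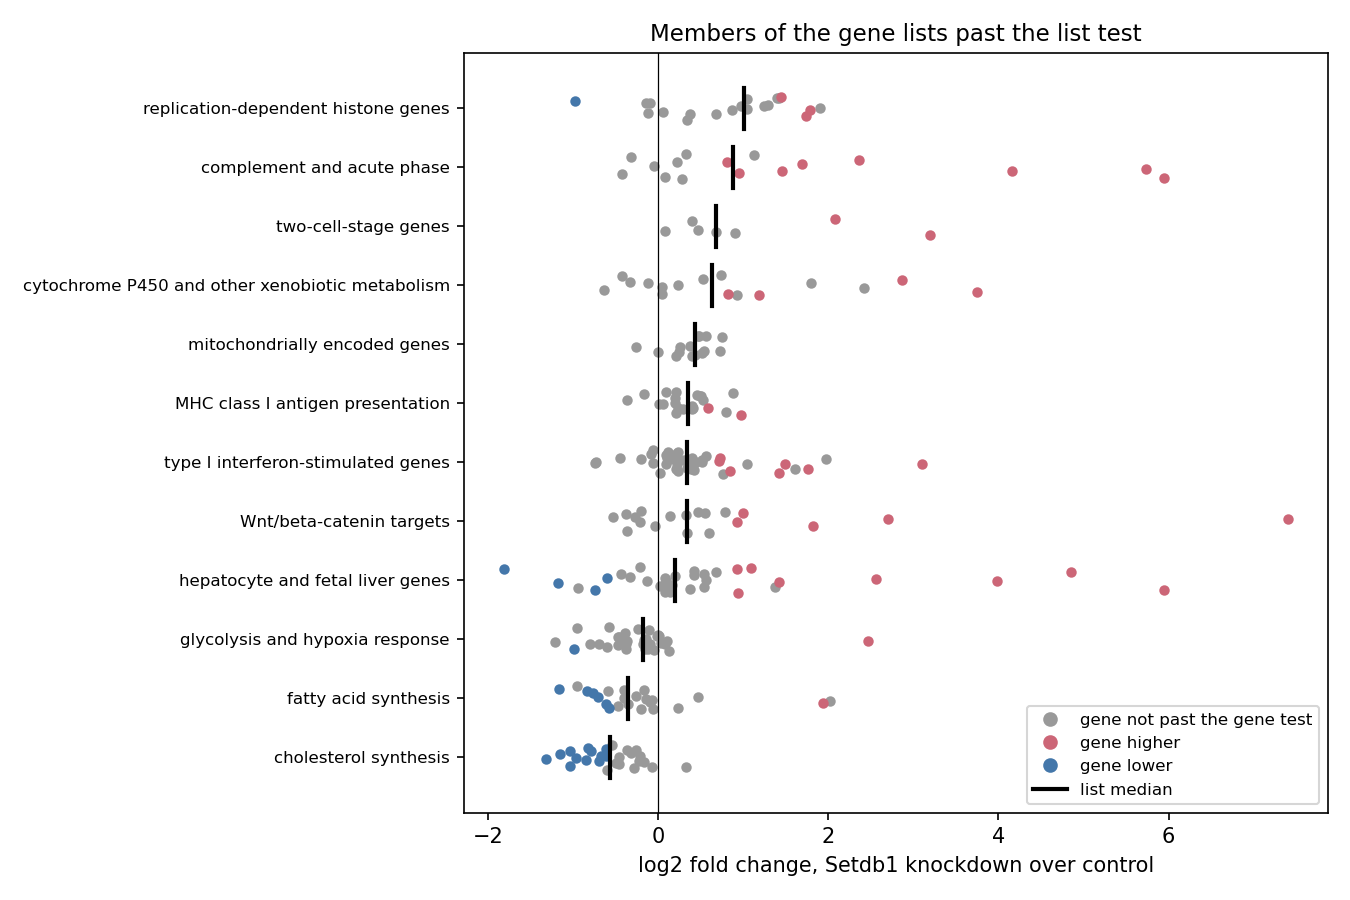
Log2 fold change (Setdb1 knockdown over control) of each tested member of the 12 gene lists past the list test, one point per gene, red for higher, blue for lower and grey for not past the gene test, with a black bar at each list's median. Cholesterol synthesis has its median at -0.571 and the histone genes at 1.008; the point at 7.41 among the Wnt/beta-catenin targets is Apcdd1, which has 0 control counts, so its position depends on the prior count.

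Genes of the H3K9 methylation and heterochromatin machinery did not move as a list (camera adjusted p = 0.33), with 3 higher, 2 lower and 24 neither of 29 tested, and the same numbers adjusted over the list alone. Mbd1, a methyl-CpG binding protein, rose from 85.2 ± 11.6 to 296 ± 33.9 CPM (log2 fold change 1.80, SE 0.155, adjusted p = 3.033e-04), and Atf7ip, a cofactor that binds Setdb1, rose by 1.09. Besides Setdb1, Suv39h2, another H3K9 methyltransferase, fell by 0.83 with all libraries, with adjusted p-values of 0.0613 to 0.0856 when any library but control 1 was left out. Imprinted genes were not called as a list (2 higher, Grb10 and Igf2, 0 lower and 13 neither of 15, 3 higher adjusted over the list alone, adjusted p = 0.187). Germline genes had 1 higher and 0 lower of 5 tested (camera adjusted p = 0.407, 1 higher adjusted over the list alone). They passed upward without control 2 and without the low-count filter (camera adjusted p = 0.0296 without the filter). Beta protocadherins had 1 higher and 0 lower of 5 (camera adjusted p = 0.407, 1 higher and 1 lower adjusted over the list alone). Their median log2 fold change was -0.567, with 4 below 0 and 1 above. Against the control mean the median was 0.018 in knockdown 1 and -0.863 in knockdown 2. The alpha and gamma protocadherins, with 3 tested members, 2 of them higher, were too few for the list test. Among 310 tested zinc finger genes named Zfp, 4 rose and 2 fell (adjusted p = 0.461, 0 adjusted over the list alone, but adjusted p = 0.00711 downward without control 1), led by Zfp600 (1.93), Zfp747 (0.93), Zfp467 (1.18) and Zfp292 (-0.77, not past the test without knockdown 2, adjusted p = 0.0945). These Zfp genes, Atf7ip and Suv39h2 did not pass on log2(TPM + 1) (adjusted p from 0.074 to 0.219). Zfp600, with 15.23 and 12.48 expected counts in the controls, and Zfp747 had fractional counts in all 4 libraries, so their values are less certain.

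The files also hold 60983 loci named only by chromosome, start, end and strand, and of the 1038 with enough counts to test 204 were higher in the knockdown and 45 lower, while most of the others lay below the control. Over all tested loci 666 had a negative and 372 a positive log2 fold change (median -0.295), and the 789 loci not called summed to 0.806 times the control level. All have lengths that are multiples of 3, between 216 and 5553 bp. Their names resemble those of catalogues of viral element reading frames, which was not checked here, and the files do not state what the loci are. Their test was added after the names had been seen. Together they took 0.355% and 0.417% of the counts in the controls and 0.359% and 0.379% in the knockdown libraries. Of the tested loci, 19.7% were higher and 4.34% lower at an adjusted p under 0.05 among loci, in an edgeR fit of genes and loci together. Of the tested genes, 4.2% were higher and 1.76% lower, adjusted among genes in their own fit, so the shares of loci and genes rest on unlike unadjusted cutoffs. The filter matters too, since 55 of the 204 higher loci had 0 control counts and entered the test only through the knockdown libraries. Among genes this held for 19 of the 538 higher. Loci with 0 knockdown counts could likewise enter through the controls alone. When tested loci within 1 kb are joined they form 845 elements, of which 121 held higher and 41 held lower loci. The 204 higher loci summed to 2774 and 2566 expected counts in the controls and to 15155 and 14953 in the knockdown libraries, while all loci of the files together came to 0.956 times the control level.

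Most tested loci lay outside annotated genes, 83.3% of the higher, 68.9% of the lower and 69.5% of the other loci. By the GENCODE M21 annotation 170 of the higher loci were intergenic, 24 lay in introns of genes on the opposite strand, 9 in introns on the same strand, 1 on an exon of the opposite strand and 0 on an exon of the same strand. The smallest p belonged to a locus on chromosome 4 (32032217 to 32034169, minus strand, GRCm38, 8749 bp from Map3k7), with 47.6 and 44.3 expected counts in the controls and 925 and 783 in the knockdown libraries (2.33 ± 0.176 against 43.9 ± 4.92 CPM, log2 fold change 4.23, SE 0.209, edgeR adjusted p = 4.521e-06). Next came a locus on chromosome 6 (4177317 to 4178396, plus strand), with 13 rounded counts in the controls and 457 in the knockdown libraries (ratio 35.1, 95% counting interval 20.3 to 66.4), and one on chromosome 15 (97485069 to 97486508, minus strand), with 1 and 205 (ratio 205, 36.3 to 8120). Among loci with whole counts in every library the smallest p was on chromosome 2 (81989976 to 81990374, plus strand), with 0 counts in the controls and 181 and 152 in the knockdown libraries, at least 111-fold higher against a floor of 3 control counts over the group. These loci were chosen by p after the data were seen, and counting intervals and floors cover counting error only. Most loci hold fractional counts, 11 of the 204 higher loci being whole in all libraries, so the split of reads among near-identical copies is uncertain. The number of lower loci moved with single libraries, to 98 without control 1, 5 without control 2 and 26 without knockdown 1, and was 18 in DESeq2, and without the low-count filter 25 loci were higher and 0 lower.

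**Figure D3:**
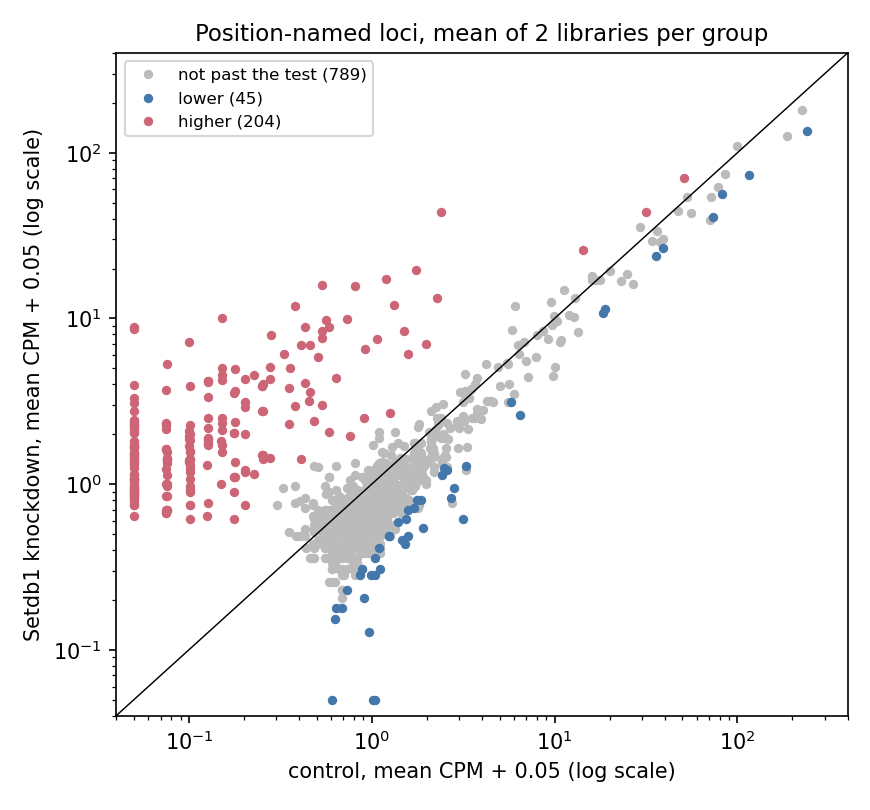
Mean CPM (with 0.05 added, log scales) of the 1038 tested position-named loci in the 2 control libraries (x axis) and the 2 Setdb1 knockdown libraries (y axis), with the line of equal values. The 204 higher loci (red) include 55 with 0 control counts at the left edge, and 45 loci are lower (blue).

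Expression of markers of other cell types was checked because a culture can hold other cells. The fibroblast or stellate list had 1 gene higher and 1 lower of 5 tested (adjusted p = 0.438, the same adjusted over the list alone). The macrophage or other leukocyte list had 0 called of 5 (adjusted p = 0.632, 2 higher and 1 lower adjusted over the list alone), and the endothelial list 0 of 5 (adjusted p = 0.407, 1 higher adjusted over the list alone). Cytosolic ribosomal protein genes had 0 called of 78 and an adjusted p of 0.0517, with a median of -0.094. This list passed downward in several other settings, at an adjusted p of 0.00418 and a median of -0.201 with the length and GC correction, 0.016 in DESeq2, 0.00301 without control 1 and 0.017 without knockdown 1.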

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

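The joint fit of genes and loci and the length and GC correction, and all settings for loci, were added after the data had been seen. Without the low-count filter the edgeR fit of 21511 genes had 2 prior degrees of freedom and called 0 genes, so 0 higher, 0 lower and 0 of the 84 named genes (smallest adjusted p 0.088, 3379 at an unadjusted p under 0.05). Setdb1 then stood at -2.49 with an adjusted p of 0.0877, 5 lists were lower, and 25 loci were higher and 0 lower. On log2(TPM + 1) limma called 334 genes, 245 higher and 89 lower, with 55 of the named genes and 5 lower lists. In DESeq2 5 lists and 18 loci were lower, and the length and GC correction also gave 5 lower lists. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry called 0 and 0. The added lower lists were G2/M and mitosis and cytosolic ribosomal proteins in each case. The cause was not tested for any of these.

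With a single library left out, a group of 1 was assumed to vary like the other group. Each of these fits, and the replicate block below, gave a far smaller smallest adjusted p than the main fit, with fewer residual degrees of freedom. Calls kept in them are therefore no sign that a result is stable. Calls then ranged from 740 to 1677 genes, with 543 to 982 higher and 197 to 695 lower. Setdb1 ranged from -2.67 to -2.32, the named genes that kept their call from 76 to 84, the lists from 6 to 8 higher and 3 to 5 lower, and the loci from 195 to 255 higher and 5 to 98 lower. Of 84 named genes, 10 lost their call in at least 1 of these fits (Suv39h2, Zbp1, Psme2, Hist1h2be, Gsta4, Fth1, Zfp292, Vegfa, Ptpn14 and Asap1), and 53 kept it in every setting but the missing filter. No named gene or called list turned its direction in any setting. The lists of interferon-stimulated, MHC class I, histone, complement and cholesterol genes passed whichever library was left out. The shared numbers 1 and 2 are not said to pair the libraries. With them as a replicate block 862 genes were called, 584 higher and 278 lower, with Fth1 alone of the named genes lost, 723 of them shared with the fit without it, and the deviations of same-numbered libraries correlated at -0.183 across genes.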

Other observations

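Several other gene groups held changes in both directions. Among 37 tested mesenchymal and extracellular matrix genes 8 rose, 2 fell and 27 did not pass (camera adjusted p = 0.407, 10 higher and 5 lower adjusted over the list alone). The gelatinase Mmp9 rose from 6.08 ± 0.109 to 51.8 ± 18.0 CPM (log2 fold change 3.09, SE 0.255, edgeR adjusted p = 2.347e-04), the lysyl oxidase Loxl2 by 3.43 and vimentin (Vim) by 1.12, while Col4a1 fell by 1.58. Epithelial and biliary genes had 3 higher and 3 lower of 23 (adjusted p = 0.95, 5 and 3 adjusted over the list alone), with Epcam (1.06) and Cldn1 (1.64) higher and Cldn2 (-1.88) and Itga6 (-0.79) lower. Inflammatory cytokine and NF-kappaB genes had 3 higher and 3 lower of 35 (adjusted p = 0.24, 8 and 4 adjusted over the list alone). The chemokine Ccl5, with 7 control counts, rose by 3.497 and the interleukin 1 antagonist Il1rn by 1.07, while Cxcl3 (-1.20) and Cd274 (-1.57) fell. NRF2 target and glutathione genes had 3 higher and 3 lower of 32 (adjusted p = 0.904, 4 and 4 adjusted over the list alone), with Gstp2 (3.28) and the epoxide hydrolase Ephx1 (1.54) higher and Osgin1 (-1.07) and Gsta4 (-1.29) lower. YAP/TEAD targets had 1 higher (Ptpn14, 1.29) and 2 lower (Nt5e, -1.72, and Asap1, -0.61) of 23 (adjusted p = 0.774, the same adjusted over the list alone). Iron handling genes had 3 higher (Cp, Lpcat3 at 0.84 and the ferritin heavy chain Fth1 at 0.59) and 0 lower of 19 (adjusted p = 0.632, the same adjusted over the list alone). Gsta4, Ptpn14, Asap1 and Fth1 each lost their call in at least 1 fit with a library left out. On log2(TPM + 1) Loxl2 (0.77, adjusted p = 0.0896), Cldn1 (0.074), Itga6 (0.0581), Asap1 (0.0634), Fth1 (0.134) and Ptpn14 (0.19) did not pass, nor did Cldn1 (0.0542) and Fth1 (0.0687) with the length and GC correction.

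The lists of cell division, survival and energy metabolism were not called in the fit of the report. G2/M and mitosis genes had 0 higher and 1 lower of 42 (adjusted p = 0.0666, the same adjusted over the list alone) and G1/S and DNA replication genes 1 and 0 of 45 (adjusted p = 0.716, 0 adjusted over the list alone). The G2/M list passed downward with the length and GC correction (adjusted p = 0.0336, median -0.19), in DESeq2 (0.0321), on TPM (0.0262), without the filter (0.0296) and without knockdown 2 (0.0178). The p53 targets had 1 and 1 of 34 (adjusted p = 0.632), and apoptosis regulators 1 and 0 of 38 (adjusted p = 0.849). The latter 2 lists had the same numbers adjusted over the list alone, as did fatty acid oxidation with 1 and 1 of 29 (adjusted p = 0.518), nuclear-encoded oxidative phosphorylation with 0 and 0 of 75 (adjusted p = 0.849) and autophagy and lysosome genes with 0 and 2 of 41 (adjusted p = 0.407). Stress response genes had 0 and 2 of 41 (adjusted p = 0.407, 0 and 3 adjusted over the list alone, but adjusted p = 0.0235 downward without knockdown 1), and growth factor signalling genes 1 and 1 of 47 (adjusted p = 0.95, 1 and 0 adjusted over the list alone). The median, mean and list test differed in sign for the germline, p53, oxidative phosphorylation, mesenchymal, epithelial, YAP/TEAD and growth factor lists.

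Genes that rose often stood beside each other, and the pairs and genes named here were chosen after their values were seen. There were 62 pairs of neighbouring tested genes that both rose, against a mean of 22.5 and a highest value of 37 in 1000 permutations (p = 0.001, the smallest they can give), and 14 pairs that both fell against a mean of 4 and a highest value of 11. Without overlap or fractional counts 9 pairs both fell, which equals the highest value of 9 in 1000 permutations (mean 2.28, permutation test p = 0.002), so the lower pairs then did not exceed the permuted range. On chromosome 1 Wnt6 (log2 fold change 1.21) lies beside Wnt10a (0.93), on chromosome 8 Cdh16 beside Rrad (1.29), on chromosome 11 Ddc (0.81) beside Grb10, and on the X chromosome Gpc4 (0.84) beside Gpc3 (2.57). Several pairs are members of the same gene family, such as Gbp3 and Gbp2, Akr1c20 and Akr1c21, and Padi4 and Padi3. The permutations took no account of families. Within 10 kb of a higher locus that overlaps no exon lay 8 of 538 higher genes (1.49%) and 18 of 12274 other genes (0.147%), an odds ratio of 10.3 (95% interval 3.85 to 25; Fisher's exact p = 7.33e-06, adjusted over 4 tests 2.93e-05). Within 50 kb the odds ratio was 4.22 (2.06 to 7.93; adjusted p = 0.000184). One of the genes within 10 kb is Klhdc7a on chromosome 4 (2.27), 4427 bp from the nearer of its 2 higher loci, both on the opposite strand. For Gpa33 (2.43) and Cd209c the locus lies on the same strand downstream of or inside the gene, so its reads could come from these genes, and without such loci the odds ratio was 9.21. If strand was not used in counting, the same could hold for Klhdc7a, whose loci lie downstream of it.

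In the weighing that follows, the tests of neighbours and nearness to higher loci, of read-through, of fractional counts, of whole knockdown counts, of nearness to unchanged loci, of nearness without read-through and of subclone differences were chosen only after the results were seen. The higher position-named loci are the first pattern. Of tested loci with whole counts in all libraries 27.5% were higher (11 of 40, exact 95% interval 14.6% to 43.9%), but a count of 0 is whole by itself, as in the controls of 3 of these 11, so this share leaves shared reads open. With whole counts asked of the knockdown libraries alone, which does not favour a rise, 22% were higher (the same 11, of 50, 11.5% to 36%). A rise was therefore also seen where no fractional count shows a division of reads. A whole count does not show that no read fits another copy, such as one without a row in the files, so shared reads stay open. On the same strand, 0.98% of the higher loci (2 of 204, 0.119% to 3.5%) lay inside or within 10 kb downstream of a higher gene. Whether strand was used in counting is not given. On either strand 15 higher loci that overlap no exon lay within 10 kb of a higher gene. Read-through from higher genes over that distance therefore accounts for few at most. For the 193 higher loci with fractional counts, how many copies rose cannot be told apart from reads shared with fewer copies, because the reads are not used here. Most tested loci did not rise, and what the reduction of Setdb1 did at the higher ones was not tested, since no measure of histone methylation is used here.

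The lower cholesterol synthesis genes are the second pattern. A trend with transcript length or GC content is argued against by the list's median of -0.595 after correcting for both, with the list still called (adjusted p = 4.83e-08). A single deviating knockdown library is argued against as well, since the library nearer to the controls had a median of -0.538. A difference of subclone or culture that goes with the groups cannot be told apart from the knockdown, because there are 2 libraries per group and no label ties them to separate cultures or to more than one shRNA. The reduction of Setdb1 itself stays among the open explanations, untested.

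The third pattern is the closeness of higher genes to each other and to higher loci. A gain of copy number in the knockdown cells would raise the genes around them, but the other 1052 tested genes within 1 Mb of the neighbouring pairs had a median log2 fold change of 0.01 (bootstrap 95% interval -0.016 to 0.035). Taken over all these regions together, this median argues against gains at most of them. Gains at a few regions, or over shorter stretches, would not show in it. Reads shared between neighbours are argued against, since 34 pairs remained without overlap or fractional counts, above the highest of 1000 permutations under the same limits (27). Pairs of the same gene family were not set apart and are counted among these 34. They include Wnt6 and Wnt10a, Abca8b and Abca8a, Akr1c20 and Akr1c21, Sprr2e and Sprr2g, and Gbp3 and Gbp2. Padi4 and Padi3, P2rx7 and P2rx4, Slco1a6 and Slco1a5, and Gpc4 and Gpc3 are others. Whether the pairs without them would still lie above the permuted range was not tested, so the excess may rest on families. Closeness to loci of any kind is argued against by the odds ratios to unchanged loci, 0.818 within 10 kb (95% interval 0.294 to 1.83) and 1.32 within 50 kb (0.844 to 1.98), which lie below the intervals for higher loci, at 50 kb by little. For read-through from the genes into the loci, loci on the same strand inside or downstream of the gene were left out. Then 6 of 538 higher and 15 of 12274 other genes were near (odds ratio 9.21, 95% interval 2.92 to 25.3, Fisher's exact p = 0.000169). This argues against read-through only if strand was used in counting, which is not given. Downstream of Klhdc7a, Olfr417, Gm13283 and 4933427I04Rik lie higher loci labelled as on the opposite strand, so this test cannot decide. Read-through between neighbouring genes or into the loci, gains of copy number at a few regions and a subclone difference stay open. So does the reduction of Setdb1 itself, and no mechanism was tested.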
